A study of Danio rerio with 6 samples.

How the data were processed

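The deposited table holds 25920 genes with read counts, FPKM and TPM for each of the 6 libraries. Per the file headers the deposited values are read counts, and since 15.2 to 16.0% of them are not whole they were read here as estimated counts. These deposited estimated counts were not scaled by the authors to a common total, and a value that is not whole was taken to hold reads divided among similar genes. A gene with such a value in any library is said below to include shared reads. How large the shared part was, and whether it had another source, was not measured. FPKM and TPM were calculated by the authors, and FPKM served only to derive the gene length used below. The group means that the authors deposited were not analysed here. Per the submitters' processing notes STAR 2.7.1a, featureCounts 1.6.0 and edgeR were used with build GRCz11; the notes give them no roles, and do not state the annotation, the strand setting or the counting rules.

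Counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr with the group factor, which left 22092 genes, TMM scaling factors, and a quasi-likelihood F test of DAPT minus DMSO with 4 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over the genes tested, at a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were scaled with the TMM factors. The biological coefficient of variation was 6.82%. The chi-square per gene against counting noise was 6.22 to 10.8 between DMSO libraries and 1.96 to 4.46 between DAPT libraries. DMSO libraries thus differed more from each other than DAPT libraries did. The log2 fold change had a Spearman correlation of -0.0824 with gene length and 0.179 with mean log2 CPM. In 12554 genes (56.8%) the values of the groups did not overlap, where chance gives 10%.

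Before the data were examined 42 gene lists were written, with 714 entries of which 710 were found, and tested with camera at a preset correlation of 0.01, adjusted over the 42. Alternatives were camera with an estimated correlation and fry (limma 3.58.1). Genes named were taken from a rule also written before the data were examined: all members of the Notch receptor and ligand, Notch target and ErbB lists; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 10 CPM, groups that do not overlap and a gene symbol; up to 4 members of each list with the smallest p; and the 5 most counted genes. The value of 1 gene that the rule names, and the counts and test of the gamma-secretase subunit list, are not reported here, though the list is among the 42. Any gene outside it is said in the text to have been chosen after its values were seen. After the data were examined 6 gene families were chosen from the genes with large changes, so the camera tests run on them restate that choice and are not given. A complement family was also tried and dropped, since its name pattern took in unrelated genes such as c6ast4. Scaling by library totals alone was an alternative added after the data were examined. DESeq2 1.42.0 and limma-voom were other alternatives.

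In 10 simulations with known changes, of about 21922 genes each, 59.7% of genes changed by 0.5 on the log2 scale were recovered, 88.7% of those changed by 1 and 99.4% of those changed by 2, and 9.43% of calls were false. That is more than the 5% that the threshold aims at. Each simulation changed only 200 genes and the cell cycle list, whereas 46.6% of genes were called on the deposited counts. The shares recovered and falsely called therefore do not carry over to those calls, of which more than 5% could be false. A first version ran 1 simulation with a limit of 10% on false calls. Gene-wise and trended dispersions were then tried, the gene-wise ones, which gave more false calls, were kept, and for the 10 simulations the limit was raised to 12%. The cell cycle list, changed in each simulation, was called in 10 of 10.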

Results

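RNA was sequenced from zebrafish at 96 hours post fertilization (hpf) that had been kept from 60 hpf in either the solvent DMSO or 100 µM DAPT. DAPT is an inhibitor of gamma-secretase, the protease that releases the active intracellular part of Notch receptors. The fish carried Tg(myl7:mCherry), a transgene that marks heart muscle cells in red. There were 3 libraries per group. The labels name hearts as the tissue, while the series' own design text speaks of collected embryos. DMSO libraries held 20542526 to 20656622 counts and DAPT libraries 21439366 to 21808573. No label says that the 3 libraries of a group came from separate clutches, so p-values measure the spread between these libraries, which may be technical. Replicate libraries of a group correlated at r = 0.989 to 0.994 over genes on log2 CPM (counts scaled to a common library total), and libraries of different groups at 0.958 to 0.968. The first principal component carried 75.3% of the variance and set the DMSO libraries apart from the DAPT libraries. The second carried 7.99%. Values below are mean CPM ± SD over 3 libraries per group. Log2 fold changes are DAPT minus DMSO and are given ± standard error.

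The series title concerns uneven Erbb2 expression and the placing of heart muscle cells, and its single comparison asks which transcripts differ after gamma-secretase inhibition. Among the largest rises were those of the cytochrome P450 gene cyp2k18, the glucuronosyltransferase gene ugt2a4, the low-oxygen gene egln3 and the matrix protease genes mmp13a and mmp9. Among the largest falls were those of the retinal gene rlbp1a and the digestive enzyme genes amy2a and ela2l. The gene cyp2k18 rose from 4.03 ± 0.886 to 190.3 ± 22.1 CPM, a log2 fold change of 5.56 ± 0.13. The glucuronosyltransferase genes ugt2a4 and ugt1a1 rose by 5.03 ± 0.08 and 2.77 ± 0.07. Their cosubstrate is made by the enzyme encoded by ugdh, which rose by 2.61 ± 0.07. Other large rises were those of map1lc3cl at 3.72 ± 0.16, the collagenase gene mmp13a (from 31.6 ± 2.05 to 290.3 ± 76.0 CPM), the transporter gene abcc12 at 3.12 ± 0.09, the prolyl hydroxylase gene egln3 at 3.10 ± 0.10, the gelatinase gene mmp9 at 2.61 ± 0.14, and the chaperone gene hsp70.1 at 2.61 ± 0.38, which was 3.34 without DMSO replicate 1. The largest fall among named genes past the level filter was in rlbp1a, which encodes a retinaldehyde-binding protein and went from 32.0 ± 8.68 to 1.39 ± 0.133 CPM, a log2 fold change of -4.52 ± 0.23. It was followed by dicp1.5-6 at -4.37 ± 0.11, the transglutaminase gene tgm1l3 at -4.06 ± 0.15, c6ast4 at -3.52 ± 0.12, lgals3bpb at -3.49 ± 0.12, the ependymin gene epd at -3.48 ± 0.08 and serpinb1l4 at -3.04 ± 0.15. The digestive enzyme genes amy2a, ela2l and prss59.1 changed by -3.41 ± 0.10, -3.41 ± 0.11 and -3.29 ± 0.12. Adjusted p for these 20 genes reached at most 0.000153, in hsp70.1, whose DMSO libraries spread widely (455 ± 321 CPM against 2789 ± 539 with DAPT). Of 22092 genes tested with edgeR's quasi-likelihood test, 10302 (46.6%) passed an adjusted p of 0.05, 4940 higher and 5362 lower with DAPT. At a fold of at least 2 there were 531 higher and 1257 lower. The split depended on the scaling: 48.0% of the called genes were higher with TMM factors, and 32.5% with library totals alone, which moved the median of all genes by -0.098 on the log2 scale. Against a null of a 2-fold change or less, 204 genes were higher and 455 lower. Counts of cyp2k18, ugt2a4, ugt1a1, map1lc3cl, hsp70.1, dicp1.5-6, tgm1l3, lgals3bpb, serpinb1l4 and prss59.1 were not all whole. They were taken to include reads shared with similar genes, which may make their single-gene values uncertain.

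Many transcripts on the list of Notch target genes fell, while those of the her4 and her15 genes tested did not pass. The repressor gene hey1 (gene ID 58008) went from 25.6 ± 1.80 to 6.37 ± 0.338 CPM (log2 fold change -2.01 ± 0.09, adjusted p = 1.13e-08), and hey2 from 17.9 ± 2.38 to 7.35 ± 0.392 CPM (-1.29 ± 0.11). The hairy-related genes her6, her8a, her2, her12 and her9 changed by -1.04 ± 0.08, -1.92 ± 0.17, -1.70 ± 0.19, -1.46 ± 0.22 and -0.53 ± 0.09. The Notch feedback genes nrarpa and nrarpb changed by -0.95 ± 0.06 and -0.86 ± 0.10, and efnb2a, an arterial ephrin gene, by -0.72 ± 0.10. In all, 10 of 16 Notch target genes fell and the other 6 did not pass, and 11 fell when adjusted over the list alone (median log2 fold change -0.81, camera adjusted p = 2.59e-07, and adjusted p = 0.128 with an estimated correlation). The 6 were heyl at -0.77 (adjusted p = 0.0533), her4.3 at -0.54, her15.1 at -0.09, lfng at 0.05, her4.2 at 0.12 and her4.4 at 0.25. heyl passed without DAPT replicate 2 (-0.998, adjusted p = 0.0406; 0.0339 to 0.23 over its alternatives). Among these, nrarpb and the her4 and her15 genes carry reads shared with similar genes. In the same libraries 13 of 16 neural transcripts fell, with a median of -0.80.

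Among receptors and ligands of the pathway, the receptor gene notch3 (gene ID 58066), known from vascular mural cells, fell from 102 ± 7.86 to 44.9 ± 0.987 CPM (-1.19 ± 0.06, adjusted p = 5.82e-08). The ligand genes jag2b, dld and dll4 rose by 0.43 ± 0.08, 0.37 ± 0.09 and 0.26 ± 0.06, while jag1b changed by -0.37 ± 0.06. The receptor genes notch1a and notch1b had values of 0.03 ± 0.06 and -0.02 ± 0.09 and did not pass, nor did the ligand genes jag1a at -0.19 ± 0.09, dla at -0.05 ± 0.10 and dlb at -0.06 ± 0.13. With library totals alone jag1a passed at -0.29 (adjusted p = 0.0247; 0.0247 to 0.348 over its alternatives). Of 13 receptors and ligands 4 rose, 4 fell and 5 did not pass, and the list test did not pass (median log2 fold change -0.05, camera adjusted p = 0.52). The weakest of these calls were those of dlc (0.19 ± 0.06), jag2a (-0.26 ± 0.09) and notch2 (-0.18 ± 0.06). Without DAPT replicate 2 their adjusted p was 0.087, 0.107 and 0.141, and dlc and jag2a were also lost without DMSO replicate 1 (0.076 and 0.0948) or DAPT replicate 3 (0.0885 and 0.0636). The call of notch2 was lost in 5 of the 6 such fits, with an adjusted p of 0.129 and 0.0779 without DMSO replicates 1 and 2, and 0.0651 and 0.0676 without DAPT replicates 1 and 3. Over all alternatives adjusted p was 0.0149 to 0.259 for dlc, 0.00496 to 0.107 for jag2a and 0.00217 to 0.141 for notch2. Scaled by library totals, dll4 did not pass (0.16, adjusted p = 0.059; 0.00391 to 0.059 over its alternatives). The counts of jag1b and notch2 include shared reads. Of the gamma-secretase subunit genes, which encode the target of DAPT, psen2 and ncstn rose by 0.46 ± 0.07 and 0.44 ± 0.08, while aph1b at -0.08 ± 0.06 (adjusted p = 0.235) and psenen at 0.03 ± 0.07 (adjusted p = 0.785), the latter chosen after its values were seen, did not pass. With library totals alone aph1b passed at -0.18 (adjusted p = 0.021; 0.021 to 0.529 over its alternatives).

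**Figure D1:**
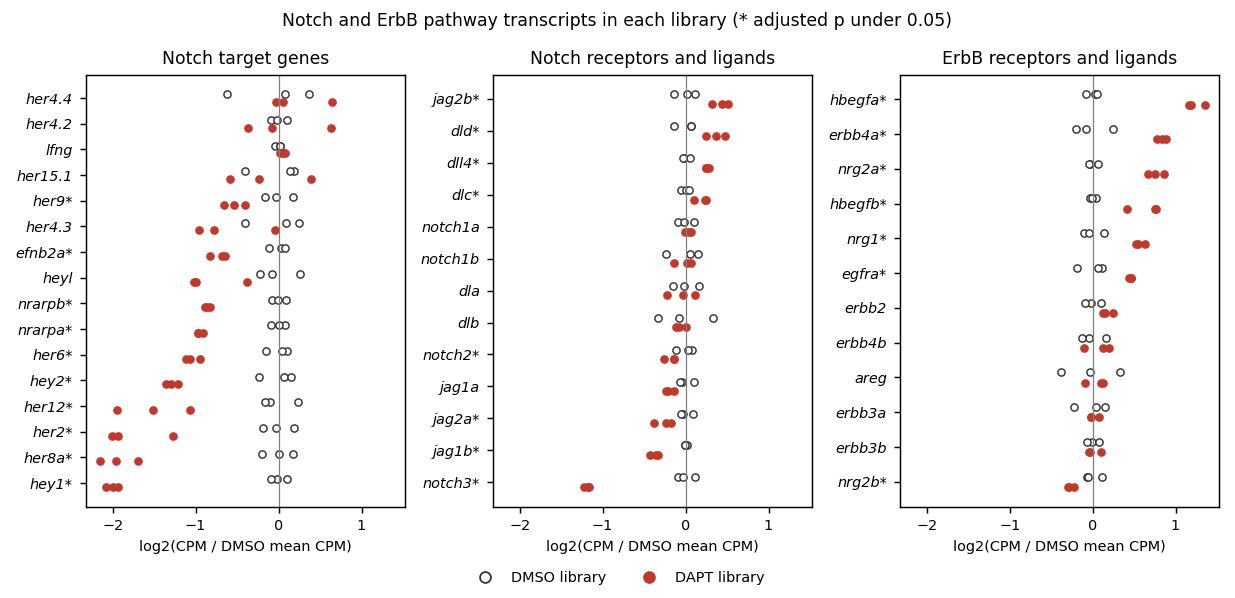
Each point is 1 library's log2 ratio of CPM to the mean CPM of the 3 DMSO libraries (horizontal axis, log2 units), with open circles for DMSO and filled circles for DAPT, for Notch target genes, Notch receptors and ligands, and ErbB receptors and ligands; an asterisk marks adjusted p under 0.05. The DAPT libraries lie to the left for hey1 (-2.01) and notch3 (-1.19) and to the right for hbegfa (1.24), while erbb2 (0.17) lies close to its DMSO values.

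The transcript of erbb2 (gene ID 386966), the ErbB receptor named in the series title, had 26.3 ± 1.78 CPM with DMSO and 29.6 ± 1.40 CPM with DAPT, a log2 fold change of 0.17 ± 0.07 that did not pass (adjusted p = 0.0659). Every library also held transcripts known from other tissues, so this value cannot be read as that of heart muscle cells alone. All 3 DAPT values of erbb2 lay above the 3 DMSO values, which chance gives for 10% of genes in either direction. In these data the groups did not overlap in 56.8% of genes, so this was common. Without DMSO replicate 1 erbb2 passed at 0.23 (adjusted p = 0.033, with 0.033 to 0.406 over its alternatives), and with library totals alone it was 0.08. Several genes for ligands of this receptor family rose. The heparin-binding ligand gene hbegfa went from 72.4 ± 3.42 to 171 ± 12.5 CPM (1.24 ± 0.07, adjusted p = 5.1e-08) and hbegfb rose by 0.65 ± 0.11. The neuregulin genes nrg2a and nrg1 rose by 0.76 ± 0.08 and 0.57 ± 0.08. Of the receptor genes, erbb4a rose from a low level of 1.42 ± 0.237 to 2.54 ± 0.0975 CPM (0.83 ± 0.19) and egfra by 0.46 ± 0.07, whereas erbb3a, erbb3b and erbb4b had values of 0.01 ± 0.08, 0.01 ± 0.06 and 0.08 ± 0.10 and did not pass, nor did the ligand gene areg at 0.05 ± 0.28. In total 6 of 12 rose, 1 fell and 5 did not pass, with 7 and 1 when adjusted over the list alone (median log2 fold change 0.32, camera adjusted p = 0.00466, and adjusted p = 0.159 with an estimated correlation). The 1 that fell was nrg2b (-0.27 ± 0.10, adjusted p = 0.0436), which passed only without DMSO replicate 2 among the 6 fits that left out a library (up to 0.134 without DMSO replicate 3; 0.0138 to 0.191 over its alternatives). Part of the egfra counts came from shared reads.

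Most of the heart muscle transcripts tested were higher with DAPT. The atrial myosin gene myh6 (gene ID 386711) rose from 126 ± 21.9 to 482 ± 49.9 CPM (1.93 ± 0.11, adjusted p = 1.14e-07) and the ventricular myosin gene myh7, formerly vmhc, from 1459 ± 210.2 to 2876 ± 95.4 CPM (0.98 ± 0.09). The troponin genes tnnt2a and tnni1b rose by 1.04 ± 0.08 and 0.86 ± 0.09. The gene myl7, whose promoter drives the transgene and which was picked after its values were seen, rose by 0.59 ± 0.08. Of 20 cardiac sarcomere transcripts 15 rose, 2 fell and 3 did not pass, with 16 and 2 when adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 1.24e-05, and adjusted p = 0.405 with an estimated correlation). Together they went from 1.07 ± 0.110% to 1.45 ± 0.0212% of all counts. The natriuretic peptide genes nppa and nppb, both made by heart muscle, rose from 362 ± 51.5 to 1064 ± 30.5 CPM (1.55 ± 0.09) and from 55.9 ± 5.14 to 149 ± 6.10 CPM (1.41 ± 0.07). Among ventricular transcripts 6 of 8 rose, including fhl2a at 0.55 ± 0.07, 1 did not pass and hey2, also on the Notch target list, fell (median log2 fold change 0.48, camera adjusted p = 0.00584, and adjusted p = 0.284 with an estimated correlation). Of 6 atrial transcripts 4 rose, including smtnl1 at 0.71 ± 0.08 and tbx5a at 0.56 ± 0.07, and 2 did not pass (median log2 fold change 0.63, camera adjusted p = 0.000156, and adjusted p = 0.128 with an estimated correlation). The counts of myh7 and nppa include shared reads.

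Among genes for cardiac transcription factors and channels more rose than fell. Rises were seen for nkx2.7 at 1.69 ± 0.09, gata5 at 1.01 ± 0.11, gata4 at 0.96 ± 0.11 and gata6 at 0.86 ± 0.09. Of the 15 transcription factor genes 10 rose and 5 did not pass (median log2 fold change 0.30, camera adjusted p = 0.000116, and adjusted p = 0.159 with an estimated correlation). The pacemaker channel gene hcn4, the sodium channel gene scn5lab and the potassium channel genes kcnq1 and kcnh6a rose by 1.99 ± 0.14, 1.96 ± 0.13, 1.66 ± 0.10 and 1.57 ± 0.11. Calcium handling and ion channel genes as a list had 10 higher, 4 lower and 3 not passing of 17 (median log2 fold change 0.41, camera adjusted p = 0.00802, and adjusted p = 0.351 with an estimated correlation). The 4 lower ones, chosen after their values were seen, were slc8a1b at -1.14 ± 0.13, hcn4l at -0.93 ± 0.17, ryr2a at -0.72 ± 0.09 and cx43, which went from 99.0 ± 6.33 to 49.6 ± 4.43 CPM. Among genes of trabeculation and cardiac jelly, the matrix layer under the endocardium, the versican gene vcana rose from 37.4 ± 2.89 to 121 ± 8.91 CPM (1.70 ± 0.07), the hyaluronan synthase gene has2 by 1.13 ± 0.09 and hapln1b by 0.65 ± 0.08, while adgrg6 changed by -0.52 ± 0.07. The related genes vcanb and hapln1a, chosen after their values were seen, changed by -0.34 ± 0.07 and -0.28 ± 0.06. Their levels with DMSO were higher, at 296 and 170 CPM. The counts of hapln1b, vcanb and actb2 include shared reads. Of the 18 genes 8 rose, 3 fell and 7 did not pass (median log2 fold change 0.14, camera adjusted p = 0.0275, and adjusted p = 0.467 with an estimated correlation). This list did not pass without DMSO replicate 3 (median 0.10, adjusted p = 0.0766) or with the stricter filter (0.11, adjusted p = 0.0847; 0.00573 to 0.467 over its alternatives). Of 19 cell adhesion and polarity genes 7 rose, among them dspa at 0.56 ± 0.06 and tjp1b at 0.57 ± 0.07, 3 fell, among them cdh11 at -0.53 ± 0.07, and 9 did not pass (median log2 fold change 0.05, camera adjusted p = 0.117). Actomyosin genes had 9 of 17 higher, including pfn1 at 0.54 ± 0.07, mylk3 at 0.55 ± 0.10, flna at 0.45 ± 0.09 and actb2 at 0.40 ± 0.07, and 8 not passing (median log2 fold change 0.16, camera adjusted p = 0.0367, and adjusted p = 0.422 with an estimated correlation). That call was lost without DMSO replicate 3 (median 0.11, adjusted p = 0.0552), with library totals alone (0.07, adjusted p = 0.0737), with the stricter filter (0.14, adjusted p = 0.113) and without the 20 most abundant genes (0.12, adjusted p = 0.0803; 0.00761 to 0.422 over its alternatives).

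Most of the vessel and endocardial lining genes tested were higher with DAPT. The junction gene cdh5 rose from 80.8 ± 4.05 to 148 ± 9.41 CPM (0.87 ± 0.06), and kdr, pecam1 and plvapb rose by 0.79 ± 0.07, 0.87 ± 0.08 and 0.67 ± 0.06. Of 23 endothelial and endocardial transcripts 15 rose, 2 fell and 6 did not pass, with 16 and 2 when adjusted over the list alone (median log2 fold change 0.43, camera adjusted p = 5e-06, and adjusted p = 0.378 with an estimated correlation). The list of tip cell and angiogenesis genes was split. It holds genes of the leading cells of vessel sprouts and other genes of vessel growth, such as vegfab. Here angpt2a, esm1, cxcr4a and vegfab rose by 2.22 ± 0.15, 1.67 ± 0.10, 1.06 ± 0.10 and 0.95 ± 0.06, and of 16 genes 6 rose, 4 fell and 6 did not pass (median log2 fold change 0.05, camera adjusted p = 0.0253, and adjusted p = 0.351 with an estimated correlation). The list did not pass without DMSO replicate 3 (0.03, adjusted p = 0.0587; 0.0018 to 0.351 over its alternatives). Of 14 atrioventricular canal and valve genes 7 rose, 3 fell and 4 did not pass, with 9 and 3 when adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.0253, and adjusted p = 0.287 with an estimated correlation). With the stricter filter of 5 CPM in 3 libraries the list did not pass (median 0.26, adjusted p = 0.0847; 0.00412 to 0.287 over its alternatives). Its genes included wnt9b at 1.32 ± 0.15, alcama at 0.53 ± 0.06 and wif1 at -0.61 ± 0.07. BMP and TGF-beta genes had 13 higher, 1 lower and 6 not passing of 20, with 14 and 1 when adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 0.00108, and adjusted p = 0.351 with an estimated correlation). Examples were the BMP ligand genes bmp6 at 0.83 ± 0.08 and bmp4 at 0.55 ± 0.06 and the BMP-induced gene id2b at 0.91 ± 0.10, and smad9, which went from 36.1 ± 6.26 to 72.1 ± 5.62 CPM and whose counts include shared reads. Among smooth muscle and mural cell genes more fell than rose, with 8 lower, 2 higher and 5 not passing of 15 (median log2 fold change -0.28, camera adjusted p = 0.00731, and adjusted p = 0.378 with an estimated correlation). The pericyte genes rgs5a and pdgfrb changed by -0.90 ± 0.05 and -0.80 ± 0.10, and the elastic fibre gene fbln5 by -0.89 ± 0.14, beside notch3. Neither the epicardium list (1 higher at 0.73 ± 0.06, aldh1a2, 1 lower at -0.46 ± 0.07, sema3d, of 10; camera adjusted p = 0.547) nor the Wnt list passed (2 higher and 2 lower of 15, 1 and 1 when adjusted over the list alone; camera adjusted p = 0.634). In the epicardium list upk3b at -0.63 ± 0.25 and tbx18 at 0.20 ± 0.08 did not pass. Without DAPT replicate 2 both passed (-0.91, adjusted p = 0.015, and 0.25, adjusted p = 0.0498), as did tbx18 without DMSO replicate 1 (0.27, adjusted p = 0.0317), against 0.015 to 0.185 and 0.0317 to 0.308 over their alternatives. In the Wnt list dkk1b rose by 0.73 ± 0.10 and wnt5b, whose counts include shared reads, by 0.17 ± 0.06, and nkd1 and notum1a changed by -0.24 ± 0.07 and -0.33 ± 0.12. Without DAPT replicate 2 nkd1 did not pass (-0.19, adjusted p = 0.0537; 0.00137 to 0.0537 over its alternatives). The call of wnt5b was lost without DMSO replicate 3 (adjusted p = 0.0575), DAPT replicate 1 (0.107) or DAPT replicate 3 (0.079), with 0.0226 to 0.304 over its alternatives. That of notum1a was lost without DMSO replicate 1 (adjusted p = 0.078), 2 (0.054) or 3 (0.118) and without DAPT replicate 2 (0.16) or 3 (0.117), with 0.0175 to 0.188 over its alternatives.

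Blood and matrix genes went both ways. Of 14 erythrocyte transcripts 8 rose, including the embryonic globin gene hbbe2 at 1.14 ± 0.08, and 6 fell, including the anion exchanger gene slc4a1a at -1.26 ± 0.07, the transcription factor gene gata1a at -1.12 ± 0.09 and the cytoskeletal gene epb41b at -0.62 ± 0.06 (camera adjusted p = 0.426). Leukocyte transcripts had 9 lower, among them the lysozyme gene lyz at -0.78 ± 0.08, coro1a at -0.42 ± 0.07 and cd74b at -3.00 ± 0.37, 7 not passing, and 1 higher, the cytokine gene il1b at 0.92 ± 0.15 (median -0.27 over 17, camera adjusted p = 0.13). In the collagen and matrix list 7 rose, 9 fell and 6 did not pass of 22, with 7 and 10 when adjusted over the list alone (camera adjusted p = 0.545). Its median was -0.11 while its mean was 0.20 and its test pointed up, since mmp13a, mmp9 and the inhibitor gene timp2b (1.53 ± 0.13) rose far while the collagen genes col6a3 (-0.75 ± 0.06) and col1a1a (-0.42 ± 0.11) fell. Without DAPT replicate 2 the list passed (median -0.08, adjusted p = 0.0316; 0.0316 to 0.83 over its alternatives).

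Transcripts known from skin, skeletal muscle, eye, liver, pancreas and the nervous system were counted in every library, and several groups of them were lower with DAPT. Which tissue they came from was not tested. The keratin gene krt4, a marker of surface epithelium, was the most counted gene of all, at 18235 ± 1319 CPM with DMSO and 17975 ± 644 with DAPT (-0.02 ± 0.08, adjusted p = 0.849). It was followed by eef1a1l1, actb2, hspa8 and col1a1a. The epidermis, skeletal muscle, eye, liver, pancreas and neural lists together took 7.28 to 7.82% of counts in the DMSO libraries and 6.43 to 6.82% in the DAPT libraries. The cardiac sarcomere list took 0.939 to 1.14% with DMSO and 1.43 to 1.47% with DAPT. All 14 eye and lens transcripts fell, from 0.981 ± 0.219% to 0.373 ± 0.00336% of counts (median log2 fold change -1.24, camera adjusted p = 7.81e-12, and adjusted p = 0.284 with an estimated correlation). The cone opsin gene opn1sw1 went from 1686 ± 473 to 346 ± 11.3 CPM (-2.28 ± 0.15) and opn1mw1 from 541 ± 172 to 79.9 ± 1.49 CPM (-2.76 ± 0.18), and opn1sw2 and the transducin gene gnat2 changed by -2.36 ± 0.17 and -2.11 ± 0.16. Of 17 pancreas and gut transcripts 15 fell and 2 rose, 1 of them fabp1b.1, a fatty acid binding protein gene of the gut, at 2.24 ± 0.07 (median log2 fold change -1.74, camera adjusted p = 2.62e-33, and adjusted p = 0.128 with an estimated correlation). Of 14 liver transcripts 12 fell and 2 did not pass, 1 of which rose when adjusted over the list alone (median log2 fold change -0.81, camera adjusted p = 4.81e-09, and adjusted p = 0.32 with an estimated correlation). The transferrin gene tfa, apoa2, serpina1 and ttr changed by -1.19 ± 0.08, -1.01 ± 0.07, -1.03 ± 0.07 and -1.82 ± 0.13. In the neural list 13 fell and 3 did not pass of 16 (median log2 fold change -0.80, camera adjusted p = 3.53e-08, and adjusted p = 0.159 with an estimated correlation). The radial glia genes fabp7a and gfap changed by -2.18 ± 0.10 and -1.30 ± 0.10, and the synaptic genes snap25a and sv2a by -0.88 ± 0.06 and -0.91 ± 0.08. Epidermis and pharyngeal epithelium went from 3.87 ± 0.204% to 3.73 ± 0.0800% of counts, with 10 higher, 3 lower and 4 not passing of 17, and 12 and 3 when adjusted over the list alone (camera adjusted p = 0.224). There krt17, evpla and krt5 changed by -1.76 ± 0.08, -0.73 ± 0.06 and -0.67 ± 0.07, and the claudin gene cldni by 0.77 ± 0.07. Skeletal muscle had 9 higher, 1 lower and 11 not passing of 21, with tnnt3a at 0.30 ± 0.05, acta1a at 0.28 ± 0.06, mylpfa at 0.56 ± 0.12 and ckma at 0.39 ± 0.09 (median 0.19, camera adjusted p = 0.128). It passed without DMSO replicate 2 (0.26, adjusted p = 0.0484; 0.0484 to 0.736 over its alternatives). The cartilage and thyroid list had 6 higher, 1 lower and 3 not passing of 10, with 6 and 2 when adjusted over the list alone (camera adjusted p = 0.301). There matn1, col11a2 and col2a1a rose by 0.64 ± 0.15, 0.47 ± 0.11 and 0.42 ± 0.10, and acana changed by -0.49 ± 0.08. Of the genes named here, eef1a1l1, actb2, krt17 and serpina1 carry shared reads.

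**Figure D2:**
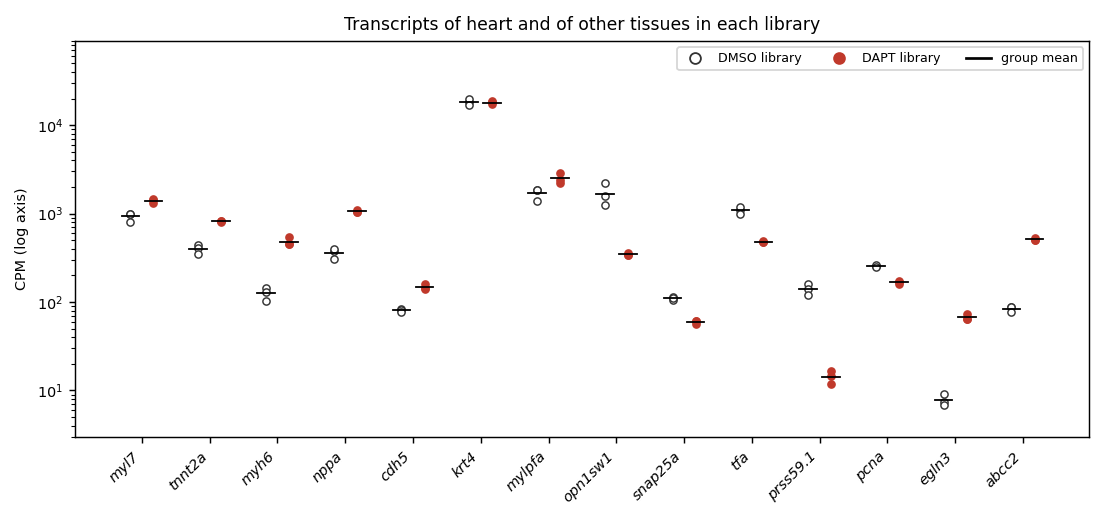
CPM on a log axis (vertical) of marker transcripts of heart, surface epithelium, skeletal muscle, eye, neurons, liver and pancreas, and of the cell cycle, low-oxygen and drug transport genes pcna, egln3 and abcc2, with 1 point per library (open for DMSO, filled for DAPT) and a bar at the mean of the 3 libraries. Heart transcripts such as myh6 (1.93 ± 0.11) were higher with DAPT, opn1sw1 (-2.28 ± 0.15) and prss59.1 (-3.29 ± 0.12) lower, and krt4 (-0.02 ± 0.08) was close to its DMSO level.

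Cell division genes fell throughout the list and ribosomal protein genes rose throughout theirs. All 22 cell cycle genes tested were lower with DAPT (median log2 fold change -0.62, camera adjusted p = 1.75e-11, and adjusted p = 0.128 with an estimated correlation). The ribonucleotide reductase genes rrm1 and rrm2 changed by -0.84 ± 0.06 and -0.64 ± 0.06, the replication clamp gene pcna went from 256 ± 4.47 to 167 ± 6.16 CPM (-0.61 ± 0.06), and top2a changed by -0.84 ± 0.08. The counts of rrm2 include shared reads. All 30 cytosolic ribosomal protein genes were higher (median log2 fold change 0.38, camera adjusted p = 5.32e-08, and adjusted p = 0.364 with an estimated correlation), including rplp1 at 0.57 ± 0.06, rpl14 at 0.57 ± 0.06, rps18 at 0.51 ± 0.05 and rpl23 at 0.48 ± 0.06, and their share went from 3.35 ± 0.0227% to 3.97 ± 0.106% of counts.

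Most of the low-oxygen genes tested rose, as did most of those of sugar breakdown. The oxygen-sensing hydroxylase gene egln3 went from 7.86 ± 1.24 to 67.5 ± 4.97 CPM (3.10 ± 0.10, adjusted p = 8.71e-10). The genes ankrd37, pfkfb3 and bnip3lb rose by 2.94 ± 0.15, 1.45 ± 0.08 and 1.28 ± 0.07. Of 16 hypoxia genes 13 rose and 3 did not pass, with 14 and 0 when adjusted over the list alone (median log2 fold change 0.69, camera adjusted p = 1.67e-12, and adjusted p = 0.159 with an estimated correlation). In glycolysis 18 of 24 rose, 3 fell and 3 did not pass, with 19 and 3 when adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 1.69e-05, and adjusted p = 0.358 with an estimated correlation). The glucose transporter gene slc2a1b, the lactate dehydrogenase gene ldha and pgk1 rose by 0.98 ± 0.08, 0.81 ± 0.06 and 0.73 ± 0.06, and the enolase gene eno1b changed by -1.31 ± 0.12. Of 22 oxidative phosphorylation and TCA cycle genes 16 rose, such as cox6c at 0.57 ± 0.07, ndufa4 at 0.52 ± 0.08, sdhc at 0.45 ± 0.06 and mdh2 at 0.33 ± 0.06, and 6 did not pass (median log2 fold change 0.22, camera adjusted p = 0.00261, and adjusted p = 0.467 with an estimated correlation). Fatty acid oxidation and lipid genes had 14 higher, 2 lower and 6 not passing of 22, with 15 and 3 when adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.0221, and adjusted p = 0.467 with an estimated correlation). With the stricter filter of 5 CPM in 3 libraries this list did not pass (median 0.20, adjusted p = 0.0913; 0.0101 to 0.467 over its alternatives). Here pdk2b, pdk4 and cd36 rose by 1.06 ± 0.16, 0.63 ± 0.07 and 0.61 ± 0.07, and apoea changed by -0.64 ± 0.06. Cholesterol synthesis genes had 3 higher, 6 lower and 9 not passing of 18, with nsdhl at -0.61 ± 0.10, hmgcs1 at -0.40 ± 0.06, ldlra at -0.38 ± 0.06 and insig1 at 0.66 ± 0.09 (camera adjusted p = 0.467).

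Among drug-handling and stress genes more rose than fell, and many did not pass. The conjugate exporter gene abcc2 went from 84.4 ± 6.06 to 512 ± 12.8 CPM (2.60 ± 0.07, adjusted p = 1.74e-10) and the cytochrome P450 gene cyp3a65 from 76.5 ± 14.4 to 397 ± 9.84 CPM (2.37 ± 0.11). The glutathione genes gstp1 and gsr rose by 1.52 ± 0.06 and 1.00 ± 0.06. Of 19 genes of the AhR and Nrf2 responses 12 rose, 3 fell and 4 did not pass, with 13 and 3 when adjusted over the list alone (median log2 fold change 0.52, camera adjusted p = 2.45e-11, and adjusted p = 0.128 with an estimated correlation). In the heat shock list 10 rose, 1 fell and 5 did not pass of 16 (median log2 fold change 0.40, camera adjusted p = 0.000346, and adjusted p = 0.378 with an estimated correlation). There hsp90aa1.2 and dnajb1b rose by 1.87 ± 0.14 and 2.08 ± 0.21, serpinh1b by 0.66 ± 0.08, and bag3 changed by -0.51 ± 0.06. Of 20 unfolded protein and integrated stress genes 9 rose, 1 fell and 10 did not pass (median log2 fold change 0.11, camera adjusted p = 0.00755, and adjusted p = 0.284 with an estimated correlation), with sesn2 at 1.05 ± 0.08, trib3 at 0.72 ± 0.06, atf4a at 0.54 ± 0.07 and ddit3 at 0.48 ± 0.05. Of 16 p53 and apoptosis genes 9 rose, 1 fell and 6 did not pass (median log2 fold change 0.26, camera adjusted p = 0.0276, and adjusted p = 0.422 with an estimated correlation), with gadd45aa at 0.67 ± 0.08, bbc3 at 0.66 ± 0.10, phlda3 at 0.47 ± 0.10 and casp8 at 0.46 ± 0.08. The p53 list did not pass without DAPT replicate 2 (median 0.24, adjusted p = 0.0507), with the stricter filter (0.23, adjusted p = 0.0901) or with library totals alone (0.16, adjusted p = 0.052; 0.00711 to 0.422 over its alternatives). Shared reads enter the counts of gstp1 and hsp90aa1.2.

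Clock genes changed in both directions. The repressor gene cry2 rose from 16.5 ± 3.96 to 40.3 ± 3.87 CPM (1.29 ± 0.13), ciarta and tefb rose by 1.48 ± 0.22 and 0.67 ± 0.10, and cry1ba changed by -0.61 ± 0.06. Of 20 clock genes 13 rose, 5 fell and 2 did not pass, and the list missed the threshold (median 0.60, camera adjusted p = 0.0518). It passed without DMSO replicate 2 (0.73, adjusted p = 2.34e-07), DMSO replicate 3 (0.46, 0.044) or DAPT replicate 3 (0.62, 0.0414), and also without a filter (0.60, 0.03), with library totals alone (0.50, 0.0315) and with fry (0.0292), against adjusted p up to 0.426 over its alternatives. Of 17 immediate early genes 8 rose, 5 fell and 4 did not pass (camera adjusted p = 0.837). Here jun rose by 0.70 ± 0.07, while fosb, nr4a1 and btg2 changed by -1.24 ± 0.07, -0.65 ± 0.05 and -0.42 ± 0.06. The median of that list was 0.11, its mean -0.03, and its test pointed down.

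Of the 42 lists, 28 passed with camera's preset correlation, 21 higher and 7 lower. With a correlation estimated for each list 0 passed, 9 had an unadjusted p under 0.05 and the lowest adjusted p was 0.128. That version of camera takes its p from the 4 residual degrees of freedom, which leaves it little power. Failing it therefore does not show that a list's genes did not move together. Fry, which asks whether a list's genes move without comparing them with other genes, called 34, among them 5 named above that camera did not: Notch receptors and ligands (adjusted p = 0.0162, lower), cell adhesion (0.00711, higher), leukocyte (0.00105, lower), cholesterol synthesis (0.02, lower) and clock genes (0.0292, higher). Where no second pair of counts is given, the counts adjusted over the list alone equalled those over all genes tested.

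**Figure D3:**
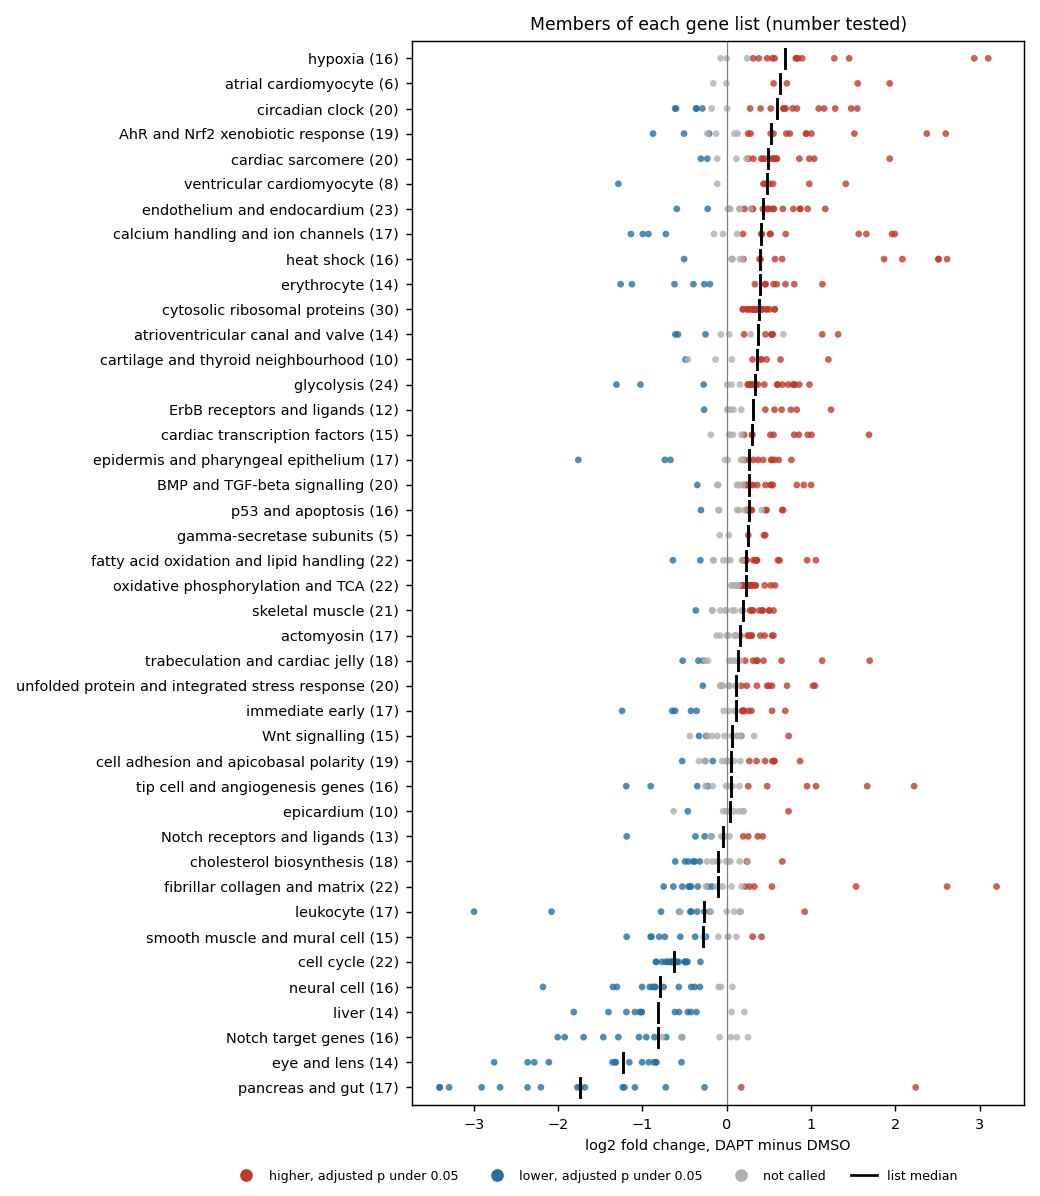
Log2 fold change, DAPT minus DMSO (horizontal axis), of each tested gene of the 42 lists, with the number tested in brackets, red for higher and blue for lower at adjusted p under 0.05, grey for not passing, and a black bar at the list's median. Medians ran from 0.69 for hypoxia genes to -1.74 for pancreas and gut genes.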

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

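Scaling by library totals alone was chosen after seeing the data, and the other alternatives before. The count of genes changed by DAPT (10302) was 8389 to 10129 with 1 library left out, 4003 to 4876 higher and 4386 to 5253 lower, and at 2-fold 511 to 592 higher and 1206 to 1418 lower. It was 8280 with DESeq2 (8186 shared with the 10302), 10237 with limma-voom, 10334 with RLE factors, 10343 without a filter, 8231 with the stricter filter, 10292 without the 20 most abundant genes and 10335 with library totals (8724 shared). Replicate numbers do not pair the libraries: 0 of 6 correlated best with the library of their own number, and a block on them gave 9716 genes (9609 shared). With that block the circadian clock list passed (median 0.61, adjusted p = 0.0108; 2.34e-07 to 0.426 over its alternatives) and nrg2b did not (-0.27, adjusted p = 0.0625; 0.0138 to 0.191). Fewer genes were called at 2-fold with the stricter filter, which tests fewer genes (312 higher, 610 lower), and with glmTreat, which tests against a 2-fold change (659, with 204 higher and 455 lower). Between 26 and 30 lists passed with 1 library left out, and 0 with an estimated correlation, which allows for genes of a list moving together. The estimate was -0.0038 for the ErbB list and -0.087 for the atrial list, below the preset 0.01. Movement of their genes together therefore does not account for the loss of these calls. The version with an estimated correlation also takes its p from only 4 residual degrees of freedom, which lowers its power for every list. The estimated correlation alters only p, not the medians. With it neither the Notch target list (median -0.81, adjusted p = 0.128) nor the ErbB list (0.32, adjusted p = 0.159) passed. With 1 library left out their medians were -0.90 to -0.76 (adjusted p 2.85e-08 to 2.28e-06) and 0.25 to 0.37 (0.00287 to 0.0101). The value of erbb2 was 0.13 to 0.23 with 1 library left out (adjusted p 0.033, without DMSO replicate 1, to 0.219). The tests of 2 lists that had not passed reversed: fibrillar collagen and matrix without DMSO replicate 3 (median -0.15, adjusted p = 0.818; median -0.0808 and adjusted p = 0.0316 without DAPT replicate 2; 0.0316 to 0.83 over its alternatives) and immediate early without DMSO replicate 1 (0.17, adjusted p = 0.955, with an adjusted p of 0.353 to 0.997 over its alternatives; the median was 0.0671 without DMSO replicate 3). The cause was not tested.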

Other observations

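The 6 gene families and both tests on heart muscle genes were chosen only after the results were seen. The families were picked from genes with large changes, so only counts and medians are given for them, since a test would restate what prompted it. Many conjugation genes rose: 22 of 36 glucuronosyltransferase genes rose and 3 fell (median log2 fold change 0.87). Among cyp2 genes 17 rose and 8 fell of 35 (0.35), and among glutathione transferase genes 13 rose and 3 fell of 21 (0.38). Examples, chosen after their values were seen, were cyp2y3, which went from 168 ± 14.2 to 718 ± 33.3 CPM (2.10 ± 0.07), gsta.1 at 1.69 ± 0.06 and mgst3b, from 124 ± 7.38 to 494 ± 30.1 CPM. Shared reads enter the counts of 29 of the 36 glucuronosyltransferase genes, 22 of the 35 cyp2 genes, cyp2y3 among them, and 7 of the 21 glutathione transferase genes, gsta.1 among them, so the calls of members may not be separate. Of 7 collagen prolyl and lysyl hydroxylase genes 5 rose (0.66), among them p4ha1b, also chosen after its values were seen, from 20.2 ± 1.41 to 107 ± 3.56 CPM. All 13 elastase, carboxypeptidase, trypsin, chymotrypsin and carboxyl ester lipase genes fell (-1.77; 4 with shared reads), as did 24 of 25 visual genes (-1.32; 4 with shared reads).

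Notch target genes fell (median -0.81), and neural transcripts fell too, so that fewer neural cells in the DAPT libraries may account for part of the fall. The median of 15 other neuron genes was -0.62 ± 0.12, past the bound of -0.41, that is 0.5 times the Notch target median, but short of the full fall. Here and below the error of a median is a standard error over genes, taken as if they were independent. The median of 11 progenitor and glia genes was -0.29 ± 0.26, too spread to decide. Neither explanation was excluded, and a block of Notch cleavage by DAPT, the explanation the design gives, stays open beside them.

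Heart muscle genes rose, and a larger share of heart tissue in the DAPT libraries may be part of it. The lists of other tissues together took 7.28 to 7.82% of counts with DMSO and 6.43 to 6.82% with DAPT, which goes with such a share. The fall was not uniform. A large part lay in the eye and lens list, which went from a mean of 0.981% with DMSO to 0.373% with DAPT. The liver, pancreas, neural and epidermis shares also fell, while the skeletal muscle share went from 1.70 to 1.84%. The skeletal muscle and epidermis lists had positive medians (0.19 and 0.26). The ratio of myh6 to myl7 changed by 1.35 ± 0.14, that of nppa by 0.97 and that of actc1a by -0.89. A share that moves all heart muscle genes alike is argued against by these ratios as the whole cause. The genes were picked after their values were seen, and the counts of nppa, actc1a, myh7 and myh7l include shared reads. Both myh6 and nppa are on the atrial list, so their ratios alone cannot tell a larger atrial part from a response. On the ventricular list the ratios of nppb and myh7 changed by 0.82 ± 0.08 and 0.40 ± 0.06. A larger atrial part would not by itself raise nppb and myh7 against myl7. The ratio of myh7l, also on that list, did not rise, so the ratios do not settle the question. The ratios of myh7l (-0.08) and cmlc1 (-0.04) leave a share open for those genes. The skeletal muscle list rose less, with a median of 0.19 ± 0.07 against 0.48 for cardiac sarcomere genes. The estimated correlation between its genes was 0.63, so an error that takes them as independent is too small. The comparison therefore cannot exclude a larger share of all striated muscle. A response of heart muscle to DAPT stays open as a hypothesis.

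Clock genes changed, and collection of the groups at another time of day or light may be a cause. Of 13 further clock-controlled genes 6 passed, above the bound of 3.25, but 46.6% of all genes passed, so the count decides nothing. A glucocorticoid response is open as well, since the median of 10 of its genes was 0.23 ± 0.19 against a bound of 0.30. Among them per1a (1.16) is also on the clock list, so the check is not separate from the pattern. The genes went both ways, with sgk1 at 0.67 but fkbp5 at -0.32 and klf9 at -0.34. These examples were chosen after their values were seen. An effect of DAPT on the clock genes cannot be told apart from either cause.

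Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 split, gave as many genes (10302, and 11840 at an unadjusted p under 0.05). The highest of the others was 0 with edgeR, with 122 to 331 genes at an unadjusted p under 0.05. Each of the other splits puts libraries of both treatments in each group, so the treatment difference enters the spread within groups. Their low counts were therefore built in, and nothing is concluded from them. With 10 splits the share cannot fall under 0.05.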
